A study of Mus musculus with 18 samples.

How the data were processed

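Gene expression was measured with Illumina bead arrays in 3 tissues (duodenum, stomach and submandibular gland) of female Car6-/- and wild-type mice aged 2 months. The series holds 18 arrays, 3 of wild-type and 3 of Car6-/- mice for each of the 3 tissues. The series text describes 3 wild-type and 3 Car6-/- mice, so the replicates of a group were separate animals. If only these mice were used, the 3 tissues came from the same animals. The text does not say whether arrays of different tissues with the same number came from 1 animal.

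The authors deposited a table of non-normalized values with the signal intensity of 25697 probes on each array, on a linear scale and with no background subtracted. The lowest deposited intensity was 36.7 and the highest was 40788. Beside each intensity the deposited table gives a detection p-value, the p_value of the probe's signal on that array. The authors also deposited a log2 value for each probe and array. Sorted within each array, these log2 values matched the sorted values of a quantile normalization of the 6 arrays of a tissue without background subtraction. That normalization was computed from the intensities, and the largest difference was 0.00519. Values were not compared probe by probe in this check. Each of the 18 arrays correlated best with its own deposited log2 column, and the lowest of these 18 correlations was 0.995. The software used by the authors is not given in the sources used here.

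The starting point was the non-normalized intensity. For each tissue, the 6 arrays were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16. The negative controls were inferred from the detection p-values, since the table holds no control probes. A probe was kept if its detection p was under 0.01 on at least 3 of the 6 arrays. The word detected has this meaning throughout, for a detection p under 0.01. Probes were named through the platform's gene identifiers and the mouse annotation of assembly GRCm38.p6. This named 23978 probes with 16593 symbols, left 1719 probes unnamed, and found no record for the identifiers of 16 probes. A gene with several kept probes was represented by the kept probe with the highest mean, and unnamed probes stayed single.

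Wild-type and Car6-/- arrays were compared within each tissue by the moderated test of limma (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are Car6-/- over wild type on the log2 scale, with the standard error (SE) of the fit, 3 arrays against 3. Where every array of a group was undetected, the fold is given as a lower bound. It was taken from the quantile-normalized signals without background correction. It is the other group's mean over that of the undetected group, with each undetected value raised to the lowest detected value of its array where that is higher. The fitted log2 values of such genes depend on the background correction and are not measured folds. Whether the effect differed between 2 tissues was tested as an interaction contrast in a fit of all 18 arrays normalized together, with probes detected on at least 3 of the 18 arrays. This fit treated the arrays as independent, although tissues of the same animals may not be.

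There were 37 gene lists of pathways, cell types and the Car6 neighbourhood, with 714 names, of which 626 were on the array. They were written from general knowledge of these tissues before the data were examined, as were the tests, the filter and the rule for named genes. Lists with at least 5 measured genes were tested with camera (a preset correlation between genes of 0.01, and an estimated correlation) and with fry, each adjusted over the lists of a tissue. Camera asks whether the genes of a list shift on balance in a single direction relative to other genes. Fry asks whether they shift on balance in a single direction, without comparison to other genes. The counts of list members past the threshold were also adjusted over the list alone.

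Named genes were chosen by rule. In each tissue these were Car6, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with no overlap between the groups, and up to 2 members past the threshold from each list. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p in that direction were named with their values. Genes past the threshold in 2 or more tissues, and the 5 genes with the smallest p of each interaction, were named too. Other genes that are named, apart from members of lists given as examples, were chosen after their values were seen.

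Replicate numbers were checked for pairing by the correlation, across genes, of the deviations of same-numbered wild-type and Car6-/- arrays from their group means. In the submandibular gland these correlations were 0.266, 0.520 and 0.235 for replicates 1, 2 and 3, so same-numbered arrays deviated together there. In the stomach they were -0.311, -0.258 and -0.295. With 3 arrays a genotype, chance is not excluded as the reason. The labels do not say whether the numbers pair the arrays of the 2 genotypes. The fits in the report carry no block.

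Precision was limited by the number of arrays. Between 7868 and 11808 probes were detected on an array. The pipeline was tested on simulated data that kept the spread of each gene in each tissue. The values were drawn independently for each gene and array, so correlation between genes and between arrays was not simulated. At a simulated fold change of 2, it called 73.1% of changed genes in the submandibular gland, 46.3% in the stomach and 38.8% in the duodenum. At a fold change of 1.5 these shares were 32.8%, 1.49% and 10.4%. Of the genes simulated as unchanged, 11, 4 and 2 were called in these tissues.

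Alternatives covered the normalization and background, the filter, the probe rule, the variance model, array weights, an ordinary test per gene, a replicate block, a fit of all tissues, the deposited log2 values, a minimum fold and leaving out each array in turn. After the data were seen, a term for the replicate 3 arrays and a fit without both replicate 1 arrays of the submandibular gland were added. No array was left out of the comparisons in the report. The figures were drawn with matplotlib 3.10.9.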

Results

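The data are signals of 25697 probes on 18 Illumina bead arrays, 3 for each of 6 groups: wild-type and Car6-/- submandibular gland, stomach and duodenum of female mice aged 2 months. Between 7868 and 9613 probes were detected on the submandibular arrays, 10214 to 11441 on the stomach arrays and 9648 to 11808 on the duodenal arrays. After the filter, 7074, 8556 and 8523 genes or unnamed probes were tested in these tissues. Correlations between arrays of the same group ran from 0.965 to 0.985 in the submandibular gland, from 0.931 to 0.980 in the stomach and from 0.958 to 0.990 in the duodenum. The replicate 3 arrays had a wider range of signals in every tissue. In the submandibular gland, for example, the signal exceeded by 1 in 100 probes was 55.4 to 57.1 times the median, against 35.0 to 39.7 times on the other arrays.

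The targeted gene was Car6, which encodes the secreted carbonic anhydrase VI of saliva and milk. Its probe, ILMN_1257323, gave a signal of 126 ± 28.01 (SD, n = 3) in the wild-type submandibular gland and was detected on 3 of 3 arrays. The 3 wild-type arrays gave 114, 106 and 158. In the Car6-/- submandibular gland the signal was 56.6 ± 6.41 (SD, n = 3), with values of 63.6, 55.1 and 51.0, and the probe was detected on 0 of 3 arrays. In the stomach it was 63.1 ± 2.26 in wild type and 58.4 ± 3.45 in Car6-/- mice (SD, n = 3 each). In the duodenum it was 56.4 ± 2.44 and 56.8 ± 3.15 (SD, n = 3 each). No stomach or duodenal array of either genotype gave a detected Car6 signal, so Car6 was measurable only in the wild-type submandibular gland among these 6 groups.

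**Figure D1:**
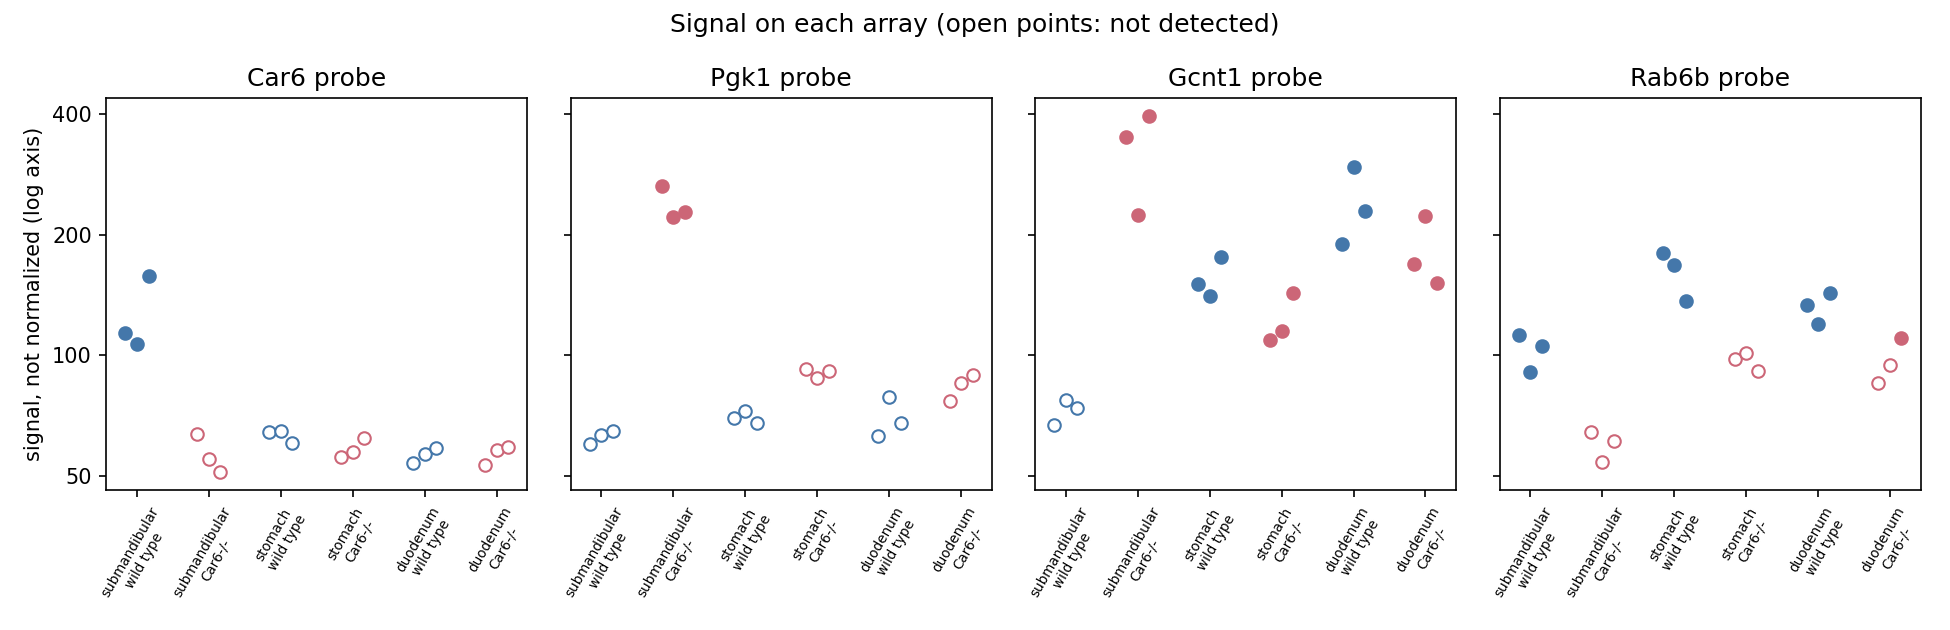
Signal before normalization of the Car6, Pgk1, Gcnt1 and Rab6b probes on each of the 18 arrays (log axis, 1 point per array, 6 groups of 3); open points were not detected. Car6 was detected on the 3 wild-type submandibular arrays, and Pgk1 on the 3 Car6-/- submandibular arrays.

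The first comparison asked which transcripts differ in the submandibular gland, a gland that makes saliva, when Car6 is missing. Car6 fell by 1.94 on the log2 scale (SE 0.17, limma adjusted p = 0.00432), at least 1.57-fold, and was lower on 3 of 3 Car6-/- arrays. Gcnt1, which encodes an enzyme that branches O-linked sugar chains, rose by 3.10 (SE 0.24, adjusted p = 0.00365), at least 3.76-fold from an undetected level in wild type. The probe of Pgk1, the gene of the glycolytic enzyme phosphoglycerate kinase, rose by 3.07 (SE 0.21, adjusted p = 0.00263), at least 2.86-fold, also from an undetected level. Rab6b, which encodes a small GTPase of Golgi traffic, fell by 1.44 (SE 0.12, adjusted p = 0.00432), at least 1.30-fold, to an undetected level. The fitted log2 values of these 4 genes depended on the background correction, and without it they were -0.93 for Car6, 1.87 for Gcnt1, 1.70 for Pgk1 and -0.64 for Rab6b.

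In all, 5 genes or probes rose and 2 fell. Brf1, which encodes a part of the initiation factor of RNA polymerase III, rose by 1.77 (SE 0.21, limma adjusted p = 0.0343). It was detected on 1 of 3 wild-type arrays, so this value too depended on the background correction, and without it the rise was 0.95. Ogfod1, the gene of a prolyl hydroxylase, rose at least 1.37-fold from an undetected level (fitted log2 1.28, SE 0.13, adjusted p = 0.00943), and did not pass without background correction (log2 0.56, adjusted p = 0.0659). The fifth, chosen for mention after its values were seen, was the unnamed probe ILMN_2958159, which rose 2.34-fold (log2 1.23, SE 0.15, adjusted p = 0.0409). All 7 had no overlap between the 3 wild-type and 3 Car6-/- arrays. Gcnt1 had a second kept probe, with a signal of 60.1 ± 3.80 in wild type and 310 ± 48.4 in Car6-/- glands (SD, n = 3 each), while its remaining probe was undetected on every array. Pgk1 gave a signal of 62.7 ± 2.35 in wild-type and 238 ± 22.98 in Car6-/- glands (SD, n = 3 each). Among genes with a symbol, those next in order by p in each direction did not pass. They were Rundc1 at 0.89 (adjusted p = 0.0665), Aldh1a1, a retinal dehydrogenase gene, at -0.78 (adjusted p = 0.153), Orc5 at -0.85 (adjusted p = 0.158) and H2-Q8 at -0.73 (adjusted p = 0.306). At an unadjusted p under 0.05 there were 682 genes, 394 higher and 288 lower. The groups did not overlap for 15.4% of genes, where chance gives 10%.

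These calls rested on few arrays. Each array left out in turn lowered the count from 7, to 0 without Car6-/- replicate 1 or 2, 4 without Car6-/- replicate 3, 3 without wild-type replicate 1 or 2, and 2 without wild-type replicate 3, partly because the filter then removed genes undetected in a whole group. Car6 and Rab6b each had a limma adjusted p of 0.0706 without Car6-/- replicate 1, 0.0832 without Car6-/- replicate 2 and 0.0420 without Car6-/- replicate 3. Ogfod1 had 0.0716 without wild-type replicate 1 and 0.0683 without wild-type replicate 3, and Brf1 and ILMN_2958159 did not pass without any single array (adjusted p from 0.0629 to 0.351). With a replicate block, Brf1 (adjusted p = 0.108) and ILMN_2958159 (adjusted p = 0.0813) no longer passed. With median scaling Gcnt1 and Pgk1 passed, and Car6 had an adjusted p of 0.0602.

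Among 23 lists tested in the submandibular gland, 9 passed with camera, 1 higher and 8 lower in Car6-/- mice. None of them passed with an estimated correlation (smallest adjusted p = 0.555 with an estimated correlation) or with fry, while 682 single genes had an unadjusted p under 0.05. Adipocyte genes fell, with a median of -0.93 (camera adjusted p = 0.000472) and 12 of 13 members lower. Examples are Adipoq, the adiponectin gene, at -1.44 and Lpl, the lipoprotein lipase gene, at -0.97. Genes of the granular convoluted tubule, the duct segment that secretes kallikreins and growth factors, fell with a median of -0.69 (adjusted p = 0.000489) and 11 of 13 lower, among them Klk1b8 at -0.97 and Egf at -0.65. Interferon response genes fell with a median of -0.54 (adjusted p = 0.000489) and 9 of 10 lower, with Isg15 at -0.73 and Gbp2 at -0.54. Macrophage and dendritic cell genes fell with a median of -0.30 (adjusted p = 0.000489) and 11 of 11 lower, and genes of antigen presentation with a median of -0.26 (adjusted p = 0.00297) and 13 of 17 lower. In these 5 lists 0 members passed by limma over all genes or adjusted over the list alone. Single arrays moved these medians. Without wild-type replicate 1 the adipocyte median was -0.35 and the granular convoluted tubule median -0.46. Without Car6-/- replicate 1 the granular convoluted tubule, interferon, macrophage and antigen presentation medians were -0.45, -0.33, -0.16 and -0.16, and without wild-type replicate 3 the interferon median was -0.31.

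Xenobiotic metabolism genes fell with a median of -0.39 (camera adjusted p = 0.00572), and 1 of 11 members, Aldh1a1, passed adjusted over the list alone. The carbonic anhydrases other than Car6 fell with a median of -0.21 (adjusted p = 0.0207) and 6 of 7 lower. Car3, which is abundant in fat, was at -1.62 and Car2 at -0.18. Antioxidant genes fell with a median of -0.16 (adjusted p = 0.0273). Genes of cholesterol synthesis rose with a median of 0.16 (adjusted p = 0.00761). Of 12 members 3 passed adjusted over the list alone, Fdps at 0.52, Dhcr7 at 0.51 and Sqle at 0.43. Adjusted p was 0.555 with an estimated correlation for each of these 9 lists. Without wild-type replicate 1 the carbonic anhydrase, antioxidant and xenobiotic lists did not pass (camera adjusted p = 0.219, 0.273 and 0.0866; medians -0.26, -0.07 and -0.18), nor did the carbonic anhydrase and antigen presentation lists without Car6-/- replicate 1 (adjusted p = 0.0847 each). The interferon and cholesterol lists did not pass without wild-type replicate 3 (adjusted p = 0.110 and 0.178), nor the antioxidant list without Car6-/- replicate 3 (adjusted p = 0.0518). With no filter on dim probes the xenobiotic, carbonic anhydrase and antioxidant lists did not pass (medians -0.02, -0.16 and -0.15, adjusted p = 0.117, 0.151 and 0.0805). The cholesterol median was 0.26 without wild-type replicate 1. Without wild-type replicate 2 the carbonic anhydrase and antioxidant medians were -0.35 and -0.24, and without wild-type replicate 3 the carbonic anhydrase and xenobiotic medians were -0.42 and -0.67.

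Markers of neighbouring tissue differed between arrays of a group. The mean of the parotid gland list was 6.65 in wild-type replicate 1 and 7.34 in Car6-/- replicate 1, against 10.83 to 12.63 on the other 4 arrays. The salivary secretory list had a mean of 9.17 in wild-type replicate 1 and 11.13 to 12.27 elsewhere, and the adipocyte list a mean of 9.21 in wild-type replicate 1 and 6.91 to 7.88 elsewhere. Without both replicate 1 arrays, a choice made after seeing the data, 3 lists passed. By limma 0 genes passed then. Brf1 (adjusted p = 0.499) and ILMN_2958159 (adjusted p = 0.587) were still tested, and the other 5 were not, as they were detected on fewer than 3 of the remaining arrays. The adipocyte median was -0.14 and the granular convoluted tubule median -0.16 without them, with an adjusted p of 0.218 each.

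**Figure D2:**
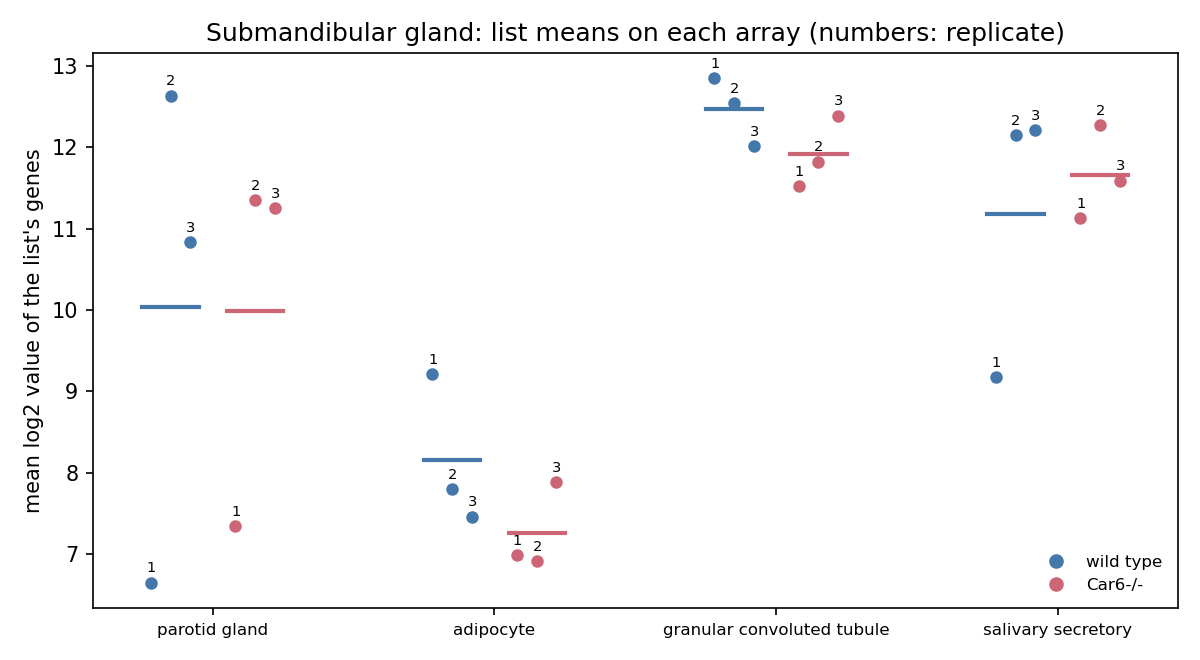
Mean log2 value of the genes of 4 lists on each submandibular array (points, numbered by replicate; bars are group means, n = 3). The replicate 1 arrays of both genotypes lie at 6.65 and 7.34 for the parotid gland list, below the other 4 arrays.

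The second comparison asked the same of the stomach. No gene passed by limma among 8556 tested (smallest adjusted p = 0.9999), with 248 genes at an unadjusted p under 0.05, 103 higher and 145 lower, and 0 by an ordinary test per gene. The 3 arrays of each genotype did not overlap for 9.01% of genes, where chance gives 10%. Among genes with a symbol, those with the smallest p were, higher in Car6-/- mice, Rtn4 at 0.65, Gpr149 at 0.73, B3galt5 at 0.86, Tgoln1 at 0.70 and Pm20d2 at 0.70. Lower were Aox3, an aldehyde oxidase gene, at -0.89, Rab6b at -1.23, Osgin1 at -0.79, Iqce at -0.67 and Fbxo44 at -0.80. Rab6b was undetected on all 3 Car6-/- stomach arrays, and Gpr149 and Pm20d2 on all 3 arrays of wild type, so these 3 values are no measured folds. The bounds were at least 1.61-fold lower for Rab6b, and at least 1.19-fold and 1.20-fold higher for Gpr149 and Pm20d2.

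Among the lists of gastric cell types, 0 passed in the stomach. Parietal cell genes had a median of 0.12, with 7 of 11 members higher, and chief cell genes a median of -0.05, with 5 of 8 lower. Genes of surface and neck mucous cells had a median of 0.14 and a mean of -0.15, and 1 of 10 members, Gkn3, a gastrokine gene of mucous neck cells, passed adjusted over the list alone at -1.98. Of 10 carbonic anhydrases other than Car6, 5 were higher and 5 lower, and 0 passed. Only the pancreatic acinar list passed of 30 tested, with a median of -1.05 (camera adjusted p = 0.00185) and 12 of 14 members lower, for example Cela2a, an elastase gene, at -3.17 (SE 1.73). Its adjusted p was 0.972 with an estimated correlation. Its mean was 12.68 in wild-type replicate 3 and 9.51 to 9.80 on the other 5 arrays, and without wild-type replicate 3 it did not pass (median -0.21, adjusted p = 0.283). By fry, the list of Car6 neighbours on chromosome 4 was lower (adjusted p = 0.0179), but not with camera (adjusted p = 0.242, and 0.945 with an estimated correlation), with 18 of 29 members lower, among them Fbxo44 and Clstn1 at -0.49.

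Other tissue markers differed between stomach arrays across genotypes. The skeletal muscle list had a mean of 9.92 in wild-type replicate 3, 10.01 in Car6-/- replicate 1 and 8.41 in Car6-/- replicate 2, against 5.36 to 5.52 on the other 3 arrays. The squamous epithelium list had a mean of 8.47 in wild-type replicate 2 and 8.26 in Car6-/- replicate 3, against 10.58 to 11.20 elsewhere. The number of lists past the threshold was 2 without wild-type replicate 2 or without Car6-/- replicate 2, and 4 without Car6-/- replicate 3.

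**Figure D3:**
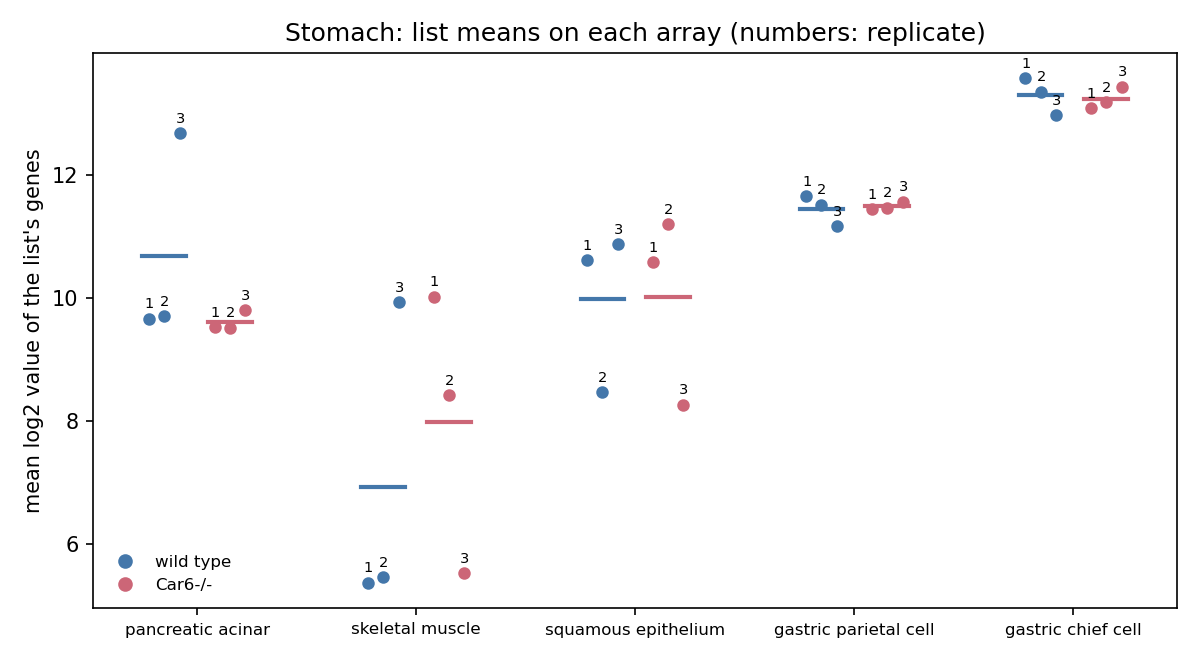
Mean log2 value of the genes of 5 lists on each stomach array (points, numbered by replicate; bars are group means, n = 3). The pancreatic acinar list stands at 12.68 in wild-type replicate 3, and the skeletal muscle list is high on 3 arrays of mixed genotype.

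The third comparison concerned the duodenum. Slurp1, which encodes a secreted Ly6-related protein, fell by 2.49 on the log2 scale (SE 0.15, limma adjusted p = 0.00473, n = 3 against 3), at least 1.91-fold, and was undetected on all 3 Car6-/- arrays. It was the single gene past the threshold among 8523 in this fit, but the count depended on the model. It was 969 with a replicate block, 848 with array weights and 603 with all 18 arrays in 1 fit. It was 420 with a term for the replicate 3 arrays, which was chosen after the data were seen. Same-numbered duodenal arrays deviated together less evenly than the submandibular ones. With camera, genes of the interferon response and of antigen presentation were higher as groups, as were genes of enterocytes, the absorptive cells, while genes of gastric mucous cells, fibroblasts and smooth muscle were lower. These 6 lists did not pass with an estimated correlation (adjusted p from 0.404 to 0.637), and wild-type replicate 3 and Car6-/- replicate 3 stood apart from their groups in some of them. At an unadjusted p under 0.05 there were 1943 genes, 968 higher and 975 lower. The groups did not overlap for 29.7% of genes, where chance gives 10%.

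Among genes with a symbol, those next in order by p in each direction did not pass. Lower were Agr2, a disulfide isomerase gene of mucus-secreting cells, at -1.23 (limma adjusted p = 0.0516), Me1, the malic enzyme gene, at -1.34, Dpt, the dermatopontin gene of the matrix, at -1.21 and Plaur, the urokinase receptor gene, at -1.01 (adjusted p = 0.0716 each). Higher were Rnf128 at 1.16 (adjusted p = 0.0783), Unc93a at 1.41 and Bak1, a gene of the cell death machinery, at 0.94 (adjusted p = 0.0886 each), Pxmp2 at 0.70 and Dgat1, whose enzyme makes triglycerides, at 1.11 (adjusted p = 0.114 each). Agr2 and Plaur were undetected on all 3 Car6-/- arrays and Unc93a on all 3 arrays of wild type, so the bounds were at least 1.32-fold and 1.26-fold lower and at least 1.33-fold higher. All 9 passed with array weights (adjusted p from 0.0122 to 0.0239) and with the term for the replicate 3 arrays (adjusted p from 0.0281 to 0.0358). The count of genes was 62 without wild-type replicate 3, with Rnf128, Dgat1, Me1 and Dpt among them, and 0 without wild-type replicate 1, without wild-type replicate 2 or without Car6-/- replicate 2. Slurp1 was not tested without a wild-type array, because its 3 detected arrays are those of wild type, and had an adjusted p of 0.0871 without Car6-/- replicate 2 and of 0.0641 by an ordinary test per gene.

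Of 31 lists tested in the duodenum, 9 passed with camera, 5 higher and 4 lower. With an estimated correlation 0 lists passed, and by fry 2 passed, while 1943 single genes had an unadjusted p under 0.05. The interferon response list rose with a median of 1.27 (camera adjusted p = 9.36e-09; adjusted p = 0.602 with an estimated correlation) and 17 of 17 members higher. The median was 1.24 with 2 members at their bounds. Of these, 16 passed adjusted over the list alone and 0 over all genes. Isg15, a ubiquitin-like protein gene, was at 2.93 (SE 0.66), Usp18, whose product removes Isg15 from proteins, at 2.68 (SE 0.70) and Oasl2 at 2.55 (SE 0.66). Antigen presentation genes rose with a median of 1.16 (adjusted p = 1.33e-07; adjusted p = 0.602 with an estimated correlation) and 21 of 21 higher, 8 of them adjusted over the list alone. Examples are Psmb9, an immunoproteasome gene, at 1.67 and Ciita, the class II transactivator gene, at 1.66. The wild-type replicate 3 array had an interferon list mean of 8.14, against 6.88 and 6.86 in the other wild-type arrays and 8.48 to 9.05 in Car6-/- arrays. Its antigen presentation mean of 9.96 lay inside the Car6-/- range of 9.91 to 10.37.

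Enterocyte genes rose with a median of 1.06 (camera adjusted p = 3.07e-06; adjusted p = 0.602 with an estimated correlation) and 15 of 15 members higher, 10 of them adjusted over the list alone and 0 over all genes. Anpep, a brush border peptidase gene, was at 1.44, Sis, the sucrase-isomaltase gene, at 1.36 and Apoa4 at 1.10. Without wild-type replicate 1 the enterocyte median was 0.67. Cell cycle genes rose with a median of 0.46 (adjusted p = 6.57e-07; adjusted p = 0.602 with an estimated correlation), 19 of 19 higher and 0 adjusted over the list alone, with Top2a at 0.72 and Mcm3 at 0.53. The B and plasma cell list rose with a median of 0.65 (adjusted p = 0.0490; adjusted p = 0.614 with an estimated correlation). Of 6 members 1 passed adjusted over the list alone, Pou2af1 at 0.92. The list did not pass without wild-type replicate 1, wild-type replicate 2 or Car6-/- replicate 3 in turn (adjusted p = 0.0627, 0.272 and 0.0827), and its median was 0.36 without the last. Nor did it pass with no filter on dim probes (median 0.11, adjusted p = 0.348), without background correction (adjusted p = 0.0610) or with the authors' values (adjusted p = 0.0560).

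Fibroblast and matrix genes fell with a median of -0.66 (camera adjusted p = 7.73e-05; adjusted p = 0.404 with an estimated correlation; fry adjusted p = 0.00851). Of 11 members 5 passed adjusted over the list alone, among them Dpt, Lum at -0.82 and Col3a1, a collagen gene, at -0.74. Smooth muscle genes fell with a median of -0.55 (adjusted p = 0.000987; adjusted p = 0.602 with an estimated correlation), 10 of 10 lower and 2 adjusted over the list alone, Tagln at -1.01 and Lmod1 at -0.60. Gastric surface and neck mucous genes fell with a median of -1.86 (adjusted p = 0.00340; adjusted p = 0.637 with an estimated correlation) and 10 of 10 lower, but 0 passed adjusted over the list alone. Muc5ac, a gastric mucin gene, was at -3.95 (SE 1.75) and Gkn1 at -2.94 (SE 1.59). Gastric chief cell genes fell with a median of -0.91 (adjusted p = 0.0381; adjusted p = 0.602 with an estimated correlation) and 7 of 7 lower, among them Pgc, the progastricsin gene, at -2.34 (SE 1.03). As fixed, this list shares Clps and Pnliprp2 with the pancreatic acinar list. Its smallest fall, -0.08, is the value of a shared member, so not all 7 mark chief cells alone. The chief cell list did not pass without wild-type replicate 1 (adjusted p = 0.0984) or wild-type replicate 3 (adjusted p = 0.0698), and its median was -0.60 without Car6-/- replicate 3. The gastric mucous list had a mean of 8.63 in Car6-/- replicate 3, 12.74 and 12.24 in the other Car6-/- arrays and 12.85 to 13.36 in wild type, and without Car6-/- replicate 3 its median was -0.62.

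**Figure D4:**
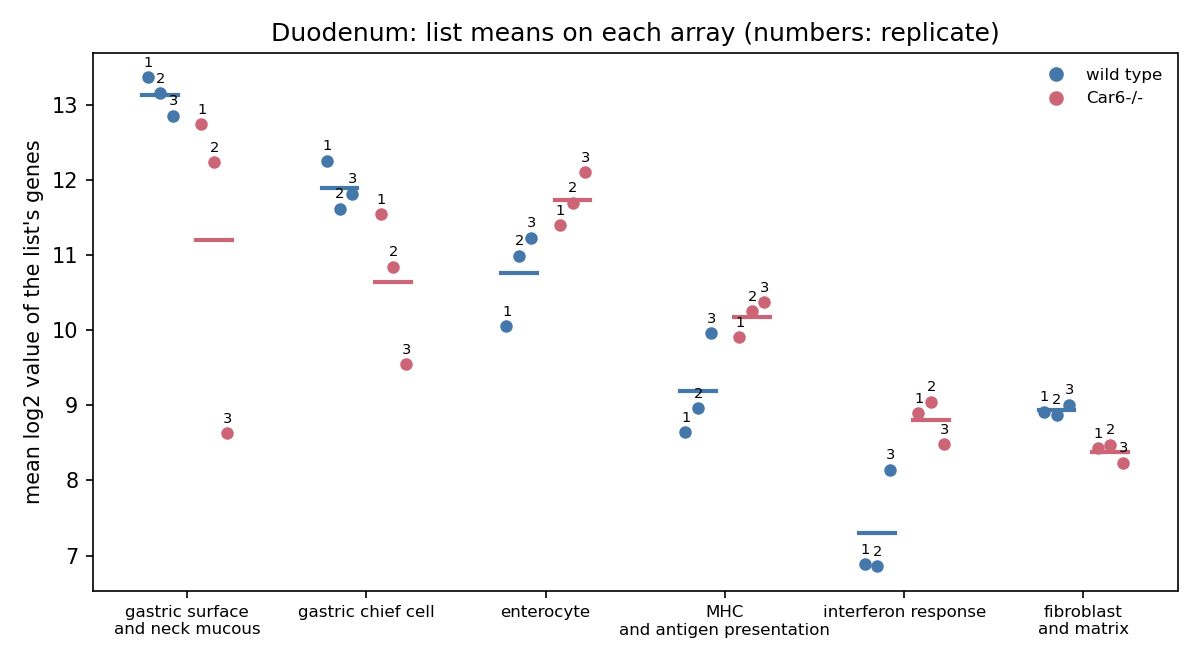
Mean log2 value of the genes of 6 lists on each duodenal array (points, numbered by replicate; bars are group means, n = 3). Car6-/- replicate 3 stands at 8.63 for the gastric surface and neck mucous list, and wild-type replicate 3 lies at 8.14 for the interferon response list, nearer to the Car6-/- arrays than the other wild-type arrays.

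The carbonic anhydrases other than Car6 were lower in the Car6-/- duodenum by fry (adjusted p = 0.00755) but not by camera (adjusted p = 0.233), with a median of -0.59, or -0.18 with Car11 and Car5b, undetected on the Car6-/- arrays, at their bounds (at least 1.34-fold and 1.13-fold lower). Of 9 members 4 were lower adjusted over the list alone, Car3 at -1.62, Car11 at -1.11, Car5b at -0.84 and Car2 at -0.74, and 2 were higher, Car4 at 0.73 and Car13 at 0.41.

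The interaction contrasts asked whether the effect of Car6 loss differed between tissues. Between submandibular gland and stomach it differed for 6 of 9682 genes (447 at an unadjusted p under 0.05). The 5 with the smallest p were Car6, with a difference of -2.86 (SE 0.21, limma adjusted p = 3.23e-06), Pgk1 at 3.38 (SE 0.26, adjusted p = 3.59e-06), Gcnt1 at 4.18 (SE 0.46, adjusted p = 0.000338), Ogfod1 at 2.02 (SE 0.23, adjusted p = 0.000351) and Olfr979, an odorant receptor gene, at 2.10 (SE 0.29, adjusted p = 0.00338). Between submandibular gland and duodenum it differed for 20 genes (1446 at an unadjusted p under 0.05), and the same 5 genes had the smallest p, with differences of 3.65 for Pgk1, -2.90 for Car6, 4.45 for Gcnt1, 1.90 for Ogfod1 and 2.09 for Olfr979. These are fitted differences and no measured folds, because Car6, Pgk1 and Olfr979 were each detected in 1 of the 6 groups, and Gcnt1 and Ogfod1 were undetected in the wild-type submandibular gland. Olfr979 did not pass with the authors' values (adjusted p = 0.999 against the stomach and 0.104 against the duodenum). Of 5 alternatives other than left-out arrays, it passed under 2 against the stomach and under 4 against the duodenum. The count of 6 was 3 without submandibular Car6-/- replicate 1. The count of 20 was 13, 6 and 63 without submandibular wild-type replicates 1, 2 and 3, and 3, 6 and 7 without Car6-/- replicates 1, 2 and 3 of that gland.

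Between stomach and duodenum the effect differed for 2 genes (1240 at an unadjusted p under 0.05). These were Krt79, a keratin gene, which had an effect of 0.45 in the stomach and -1.31 in the duodenum (adjusted p = 0.00705), and Mup6, a major urinary protein gene, with -0.03 and -3.49 (adjusted p = 0.0479). Krt79 was undetected on the duodenal Car6-/- arrays and Mup6 on all stomach arrays, so these values are fitted too. With only the 4 groups concerned neither passed (adjusted p = 0.155 each), without background correction Krt79 did not (adjusted p = 0.05003), and with no filter Mup6 did not (adjusted p = 0.142). Adap1, Mup2 and Ctrc, the chymotrypsin C gene, came next and did not pass (adjusted p = 0.0579, 0.0579 and 0.0639), but they passed with the authors' values (adjusted p = 0.0210, 0.0131 and 0.0257). Mup6 did not pass without any of the 6 stomach arrays, duodenal wild-type replicate 1 or duodenal Car6-/- replicate 2 in turn (adjusted p from 0.0655 to 0.136). Ctrc passed without duodenal wild-type replicate 1, 2 or 3 or Car6-/- replicate 1 (adjusted p from 0.00983 to 0.0272), Adap1 without duodenal wild-type replicate 2 or 3 or Car6-/- replicate 1, and Mup2 without duodenal wild-type replicate 3 or Car6-/- replicate 1. Without duodenal wild-type replicate 3 the counts were 269 against the submandibular gland and 169 against the stomach, and without duodenal Car6-/- replicate 1 they were 192 and 106. Against the submandibular gland the count was 11 without duodenal wild-type replicate 1 and 6 without Car6-/- replicate 2. Between stomach and duodenum it was 7 without duodenal wild-type replicate 2, 5 without duodenal Car6-/- replicate 3, and 1 without duodenal Car6-/- replicate 2, stomach wild-type replicate 2 or any stomach Car6-/- array.

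Across tissues, 0 of the 6596 genes tested in all 3 passed by limma in more than 1 of them. At an unadjusted p under 0.05 in all 3 tissues there were 10 genes, and 6 of them had the same direction in each. Independent tissues would give 2.86 and 0.715. With 3 wild-type and 3 Car6-/- mice described, the tissues came from the same animals unless others were used. Independence is thus not to be assumed, and these values are no firm baseline. Chosen after their values were seen, the 6 with the same direction were the unnamed probe ILMN_2958159 and the genes Rab6b, Fbxo44, Zfp87, Clstn1 and Abhd3. ILMN_2958159 had log2 fold changes of 1.23 (SE 0.15), 1.46 (SE 0.23) and 1.54 (SE 0.17) in submandibular gland, stomach and duodenum. Rab6b had -1.44 (SE 0.12), -1.23 (SE 0.23) and -1.11 (SE 0.28), the first 2 against undetected Car6-/- groups. Fbxo44 and Clstn1, both on the list of Car6 neighbours on chromosome 4, had -0.79, -0.80 and -0.94, and -0.51, -0.49 and -0.69. In the duodenum Fbxo44 was undetected on the Car6-/- arrays and fell at least 1.15-fold.

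**Figure D5:**
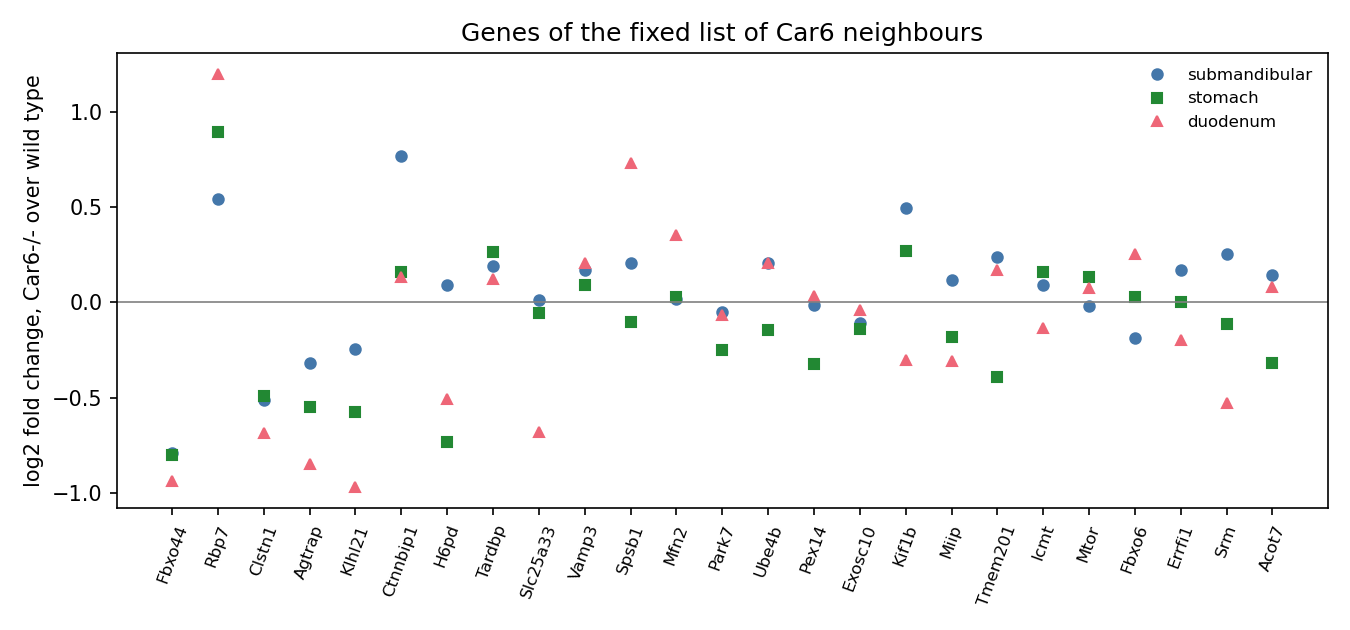
Log2 fold change, Car6-/- over wild type, of 25 genes of the list of Car6 neighbours measured in all 3 tissues (1 point per gene and tissue, ordered by combined z). Fbxo44, Clstn1, Agtrap and Klhl21 lie below 0 and Rbp7 and Ctnnbip1 above 0 in each tissue.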

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

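The chance splits, the share of gastric genes and the glycolysis genes were tested as written before their results were seen, while the other tests in this part were chosen only after the result was seen. The thresholds for reading the spread of the gastric list and the lists of intestinal and immune cells were also made stricter after a first look at their values.

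The effect of Car6 loss differed between submandibular gland and stomach by a limma interaction test for Car6 (difference -2.86), Pgk1 (3.38), Gcnt1 (4.18), Ogfod1 (2.02) and Olfr979 (2.10). Against the duodenum Car6, Pgk1, Gcnt1, Ogfod1 and Olfr979 differed by -2.90, 3.65, 4.45, 1.90 and 2.09. Between stomach and duodenum, Krt79 differed by 1.76 and Mup6 by 3.46. Each of these genes was undetected in at least 1 of the groups compared, so the differences are fitted values and not measured folds. Of 100 splits of the arrays of both tissues, the real one included, 3 gave as many genes as the real count of 20 between submandibular gland and duodenum. That share was under 0.05, but it was not adjusted over the contrasts and the highest other split gave 79, so chance was not excluded. For submandibular gland and stomach, 22 of 100 splits gave at least the real 6 genes and the highest other gave 123. For stomach and duodenum, 18 of 100 gave at least the real 2 and the highest other gave 40. Chance was not excluded for these counts either. The highest counts are several times the real ones, which points to a structure of the samples other than genotype. Of the 80 splits that part all 3 replicate pairs of the submandibular arrays, the real one included, 26 gave at least 6 genes against the stomach (highest other 69) and 2 at least 20 against the duodenum (highest other 31). These shares concern the counts and not single genes. Against the stomach, Car6, Pgk1, Gcnt1 and Ogfod1 passed by limma under all 5 alternatives, and with every array left out where they were tested.

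Within a tissue the 6 arrays allow 10 splits, too few for a share under 0.05. The real split gave 7 genes in the submandibular gland, the highest other gave 1, and 1 split of the 10 reached 7. Among the 4 splits that part all 3 replicate pairs there, the other 3 gave 1, 0 and 0 genes. For lists the real split gave 9, the highest other 10, and 3 splits reached 9. That highest split sets wild-type replicates 1 and 3 and Car6-/- replicate 1 against the rest. In the stomach the real split gave 0 genes and 1 list, which all 10 splits reached. The highest other gave 25 genes and 8 lists, and it sets wild-type replicates 1 and 2 and Car6-/- replicate 3 against the 3 arrays with a high skeletal muscle list, which points to a structure of the samples. In the duodenum the real split gave 1 gene and 9 lists, the highest others gave 0 and 11, and 1 split reached 1 gene and 4 reached 9 lists.

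The Pgk1 probe rose in the Car6-/- submandibular gland, and 7 of 25 neighbours of Car6 lay in the top 5% of genes by a z combined over 3 tissues (one-sided permutation p = 0.00016), 6 of them with 1 direction in all 3. Their list did not pass with camera in any tissue (adjusted p = 0.299, 0.242 and 0.586), but camera asks for a single direction and these genes moved both ways. By fry without regard to direction the adjusted p was 0.0455 in the submandibular gland, 0.896 in the stomach and 0.00714 in the duodenum. In the duodenum 14 of 31 lists passed that way. The tables argue against raised glycolysis as the source of the Pgk1 signal, since 12 other glycolysis genes had a median log2 fold change of 0.131 and a highest of 0.62. The probe's signal was 238 in Car6-/- and 62.7 in wild-type glands, and it was undetected on every wild-type array of the 3 tissues. Below detection it was also higher in the Car6-/- stomach (90.5 against 70.1, with no overlap). In the duodenum its mean was 83.8 in Car6-/- and 69.8 in wild-type mice, with overlap. The difference of 3.38 from the stomach thus rests in part on undetected values and is no measured size. Whether the probe reports the normal Pgk1 transcript was not tested. Pgk1 sequence in the targeted Car6 locus and other sources of the signal cannot be told apart, because the labels do not describe the allele. Chromosome of another strain flanking the locus may contribute to the neighbours, and an effect of the allele on its neighbours was not tested.

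Gastric mucous genes were lower in the Car6-/- duodenum by camera, but not with an estimated correlation (adjusted p = 0.637) or by fry (adjusted p = 0.326), and 0 members passed adjusted over the list alone. A smaller share of gastric tissue in the samples predicts that other stomach genes fall too. This was read from 101 genes on no list that were at least 16-fold higher in stomach than in submandibular gland. Of these, 73.3% were lower (median -0.61), against 47.3% of other genes on no list, just short of the 75% set before the result was seen. The duodenum played no part in the choice, so the set may hold genes that the duodenum itself expresses. A smaller gastric share would not lower those, so the shortfall cannot decide the question. A like fall in all 3 Car6-/- duodena is not what the arrays show at first sight, since their list means spanned 4.11 against a group difference of 1.92 and a wild-type span of 0.51. Without Car6-/- replicate 3 the span was 0.50, so 1 array carries it. On the stomach arrays, which were normalized separately, the mean of this list was 12.61 to 13.05. It was 12.24 and 12.74 in the other 2 Car6-/- duodena and 12.85 to 13.36 in wild-type duodena. All duodenal arrays but Car6-/- replicate 3 thus held these gastric transcripts at a level like that of the stomach. A difference in the tissue taken and a response to Car6 loss cannot be told apart, because 3 animals a group and 1 distant array leave both open.

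Interferon and antigen presentation genes were higher in the Car6-/- duodenum by camera, but not with an estimated correlation (adjusted p = 0.602 each) or by fry (adjusted p = 0.163 and 0.207). More macrophages and dendritic cells as the whole cause are argued against by a median of 0.0836 for their genes (the interferon mean was higher by 1.38, SE 0.42). A response shared by all tissues is argued against by a median of -0.54 in the submandibular gland, or -0.31 without wild-type replicate 3. The stomach median of 0.106 decides less, since it rests on wild-type replicate 3. That array had an interferon mean of 8.14, against 7.50 and 7.35 in the other wild-type stomachs and 7.73 to 7.84 in Car6-/- stomachs. A smaller gastric share and a response of the tissue cannot be told apart, because enterocyte, Paneth and goblet cell genes had medians of 1.06, 0.86 and 0.06 against 1.27, and the interferon mean exceeded theirs by 0.54 (SE 0.49), 0.62 (SE 0.31) and 1.58 (SE 0.44). Nor can more lymphocytes be told from it, since T and NK cell genes had a median of 0.82 and B and plasma cell genes of 0.65 (camera adjusted p = 0.0490, and 0.614 with an estimated correlation), and the interferon mean exceeded theirs by 0.94 each (SE 0.55 and 0.44). What stays open, untested, is a local response to Car6 loss, or to microbes or housing that differed between animals, and wild-type replicate 3 lay between the groups for the interferon list and inside the Car6-/- range for antigen presentation.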

How the results depend on the processing

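The term for replicate 3 and the fit without both replicate 1 arrays were chosen only after the result was seen, and the other alternatives were planned. No called value changed direction. Of the values for named genes, 346 kept their side of the threshold under the alternatives other than left-out arrays, 48 came to pass and 26 no longer passed. Most named genes did not pass in the main fit and had no call to lose, so the 26 all fell on called genes or probes. Among these, Brf1 passed under 7 of 14 alternatives, Ogfod1 under 10 of 13, Car6 under 11 of 13 and Slurp1 under 12 of 13. For lists these were 74, 0 and 49, and for interaction genes 58, 9 and 8. In the submandibular gland the count of 7 genes became 2 with median scaling, 4 with all 18 arrays normalized together, 30 with all 18 arrays in 1 fit, 23 with array weights and 0 with an ordinary variance per gene. It became 0 with detection on all 6 arrays, where ILMN_2958159 was still tested (adjusted p = 0.115), 0 without both replicate 1 arrays, and 0 to 4 with single arrays left out. The 9 lists became 3 without both replicate 1 arrays and 0 with an estimated correlation or fry. Car6 ran from -2.01 to -1.79 with single Car6-/- arrays left out (adjusted p 0.0420 to 0.0832), and -0.93 without background correction. In the stomach 1 gene passed with all 18 arrays in 1 fit, and the 1 list became 3 with no filter, 0 with an estimated correlation and 1 to 4 with single arrays left out.

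In the duodenum the count of 1 became 5 with no background correction, with the authors' values, or with variance trend and robust, 603 with all 18 arrays in 1 fit, 3 with no filter, 0 with detection on all 6 arrays, 848 with array weights, 4 with an ordinary variance per gene, 420 with the replicate 3 term and 0 to 62 with single arrays left out. The 9 lists became 0 with an estimated correlation. With fry 2 lists passed, the fibroblast and matrix list, which was among the 9, and the carbonic anhydrases other than Car6, which were not. Counts of differing effects ran from 3 to 8 (submandibular gland and stomach), 3 to 269 (submandibular gland and duodenum) and 1 to 169 (stomach and duodenum) with single arrays left out. With only the 4 groups concerned, the last 2 became 7 and 0. Between stomach and duodenum, 12 differed with the authors' values and 4 with no background correction. The cause was not tested for any of these beyond those named.

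With a replicate block the submandibular count was 5, with 10 lists, and only Brf1 and ILMN_2958159 changed their call. In the duodenum same-numbered arrays correlated by 0.485, 0.0871 and 0.440 for replicates 1, 2 and 3, and 5 of 6 arrays were closest to their own number. Same-numbered duodenal arrays thus deviated together less evenly, with the weakest link in replicate 2. The replicate block there gave 969 genes (418 higher, 551 lower) and 13 lists. The 9 genes named above as not passing passed under it (limma adjusted p 0.0217 to 0.0275). Stomach numbers correlated by -0.311 to -0.258, with 0 genes under the block. With same-numbered arrays of a genotype as a random replicate block (correlation 0.0839), 6, 59 and 5 effects differed, and Adap1, Mup2 and Ctrc passed between stomach and duodenum (adjusted p = 0.0398, 0.0398 and 0.0405). A slide block was not run, since no slide is given. Median scaling shifted all genes by 0.10 in the submandibular gland and 0.22 in the duodenum, and no list past the threshold changed sign relative to it. Signals near background, as for Car6 and Pgk1, limit folds to lower bounds.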

Other observations

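No test in this part was chosen after the result was seen; the genes named were examples chosen after their values were seen. In the duodenum, some lists had members on both sides, adjusted over the list alone, with 0 past the threshold over all genes. Of 15 fatty acid and triglyceride genes, 3 were higher adjusted over the list alone (Mogat2 at 1.29, Dgat1 at 1.11 and Elovl6 at 0.77, all enzymes of lipid assembly) and 3 lower (Scd1 at -1.81, Me1 at -1.34 and Acly at -0.45), with a camera adjusted p of 0.935. Among 15 endocrine genes, Ghrl, the ghrelin gene, was at -1.50 and Cck, the cholecystokinin gene, at 1.02, both past the threshold adjusted over the list alone, and Gast, the gastrin gene, was at -4.46 (SE 1.64) and was not (camera adjusted p = 0.366 for the list). Ghrl and Gast are also genes of the stomach, and gastric mucous and chief cell genes were lower in the same samples (medians -1.86 and -0.91). Car6-/- replicate 3 lay far apart for Gast, at 4.58 against 11.58 and 10.34 in the other Car6-/- arrays and 12.77 to 13.73 in wild type. Of 25 xenobiotic metabolism genes, 8 were lower adjusted over the list alone, among them Gsta3 at -1.47 and Gstm1 at -0.91, and 2 higher, among them Cyp2b10 at 1.21. The Paneth cell and antimicrobial list had 8 of 8 members higher with a median of 0.86 (adjusted p = 0.0573), among them Reg3g at 1.13.

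Pancreatic acinar genes were abundant on all 6 duodenal arrays, with list means of 13.77 to 14.59 and a median fold change of -0.08. Ctrc, the chymotrypsin C gene, was the exception at 3.75 (SE 0.71, limma adjusted p = 0.115), and it alone of 23 members passed adjusted over the list alone. In the submandibular gland, Plvap, a gene of fenestrated endothelium, was at 0.53 and passed adjusted over its list alone, as did Ctnnbip1 at 0.77 and Fbxo44 at -0.79 among 26 Car6 neighbours.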
